A study of Caenorhabditis elegans with 12 samples.

How the data were processed

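RNA sequencing of whole Caenorhabditis elegans at the late L4 stage was analysed in 12 samples, 3 for each of 4 genotypes: wild type, mir-58, mir-80 with mir-58 (the double mutant) and mir-80, mir-58 and mir-81-82 (the quadruple mutant, which lacks 4 members of the miR-58 family). Groups were taken from the sample titles. Per the labels' protocols, animals were grown on isotope-labelled bacteria, synchronised by bleaching, staged by vulval structure and extracted with TRIZOL. The labels do not say whether replicates came from separate cultures, so the p-values may measure technical spread.

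The values used are the authors' own comparisons. Their deposited table lists 16309 gene names, each with a log2 fold change and an adjusted p-value for each of the 3 mutants against wild type, per the file headers. DESeq is named in the submitters' processing notes, without a version. The aligner, the counting program, the genome build and the method of p-value adjustment were not given in the sources used here. Counts and normalised values per sample were not analysed here, so the depth per sample is unknown, no replicate error can be given, and a fold change of a gene with few reads cannot be told from that of a well-covered gene. The planned gene-level test (a quasi-likelihood fit to counts), the set tests on that fit, the replicate block, other normalisations, filters, leave-one-out fits and permuted splits were therefore not run. Matches to the microRNA seed were not analysed, because no genome sequence was used here.

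A gene was called higher or lower in a mutant when the adjusted p-value in the authors' deposited table was under 0.05. Names were matched without regard to case to Ensembl release 115 of the WBcel235 assembly by symbol or sequence name. Of the 16309 names, 15515 matched and 794 did not, and 20 names shared an annotated gene with another name. The annotation served for names, chromosomes, neighbour relations and exonic lengths, and no coordinates are given.

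The 27 gene lists were fixed before the data were examined. Each list was tested for an excess of higher calls and of lower calls over all listed genes by a one-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 54 tests of a comparison. This test replaces the planned one, and it treats genes as independent, which co-regulated genes are not, so its p-values are too small. The median of each list was placed among 10000 random lists of the same size. These could not be matched on expression. Counts adjusted over the list alone rest on p-values recovered from the adjusted ones under the assumption of a Benjamini-Hochberg adjustment over the 16309 genes. Gene families of at least 10 listed members with a common name prefix (107 families, 642 tests) were tested the same way; this test was chosen after the data were seen.

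Overlaps of calls between mutants were set beside the overlap of independent lists and the mean of 100 simulations of unchanged groups compared with the same wild type. In each simulation every group had 1 normal value per gene, and the most extreme genes were taken in the numbers called. Differences between successive genotypes are differences of the deposited log2 fold changes, in which the wild type cancels, and they have no test.

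List tests were tested on simulated data, made by shuffling the gene labels, with 1 planted list of 30 genes among 26 random ones. A list with 12 members called higher in the quadruple mutant was recovered in 50 of 50 batches, and 4 of 7800 tests of random lists passed. The planted number fixes the Fisher p-value, which was the same in every batch, so recovery was set in advance. The batches are thus not separate trials of sensitivity. Shuffling makes genes independent, so the random lists do not measure false calls among co-regulated genes. An earlier version of this trial placed 1 such list among many more random ones and did not recover it after adjustment over that larger number of tests.

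Genes were named by a rule fixed in advance: genes at the microRNA loci, all reported miR-58 family targets, the 10 highest and 10 lowest log2 fold changes per mutant among called genes (up to 8 of each are printed), and up to 4 members per list with the smallest p-values. The parts of the rule that need counts or values per sample were not applied. Some genes are also given in a mutant other than the one in which the rule picked them. Genes named outside the rule are said to be chosen after their values were seen. Alternatives were adjusted p under 0.01 and a change of at least 1.5-fold, both planned for the counts of genes changed. Their use on list counts and the other alternatives were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.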

Results

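Transcript levels were compared in whole late L4 animals of 4 Caenorhabditis elegans genotypes, 3 samples each. The miR-58 family is a group of microRNAs with a common seed. The mir-58 strain lacks 1 member, the double mutant lacks mir-80 and mir-58, and the quadruple mutant lacks mir-80, mir-58, mir-81 and mir-82. Wild type and mir-58 were collected 33 h after transfer. The multiple mutants develop more slowly, and per the labels the double mutant was collected 6 h and the quadruple mutant 15 h after wild type, so in these strains genotype and time of collection change together. The values are log2 fold changes against wild type and adjusted p-values for 16309 genes from the authors' own comparisons. Depth and the spread between replicates are unknown here.

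The targeted loci were examined first. The microRNAs themselves are not among the listed genes, so their loss was not measured. In the annotation mir-81 and mir-82 lie within T07D1.2, and the authors' deposited table gives this gene log2 fold changes of 0.33 in mir-58, 0.29 in the double and -4.39 in the quadruple mutant (adjusted p = 1.36e-22 in the last). The next gene on 1 side, glr-7, a glutamate receptor subunit gene named after its values were seen, stood at 2.85 in the quadruple mutant in the authors' deposited table (adjusted p = 1.37e-04) and at 0.26 and -0.25 in the others, where it was not called. Y67D8A.2, which contains mir-58, was at 0.10, 0.20 and -0.18 in the authors' deposited table and was not called in any mutant. Of its neighbours, named after their values were seen, T26C12.1 was called at 0.68 in mir-58 (adjusted p = 9.07e-03) and M4.1 at 0.74 in the quadruple mutant (adjusted p = 0.0207) in the authors' deposited table. No listed gene overlaps mir-80 or lies within 2 kb of it.

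The series asks how targets of miR-58 respond to loss of the family. Of the 6 listed genes on the list of reported targets, 1 rose in mir-58, 2 in the double and 3 in the quadruple mutant, and none fell. Adjusted over the list alone, 2, 2 and 3 rose. The excess of higher calls did not pass the test (Fisher's exact test, adjusted p = 0.256, 0.354 and 0.144). In mir-58 the list median was 0.36, near those of the egg laying circuit and uterus list (0.34) and of neuronal genes (0.33). The receptor gene sma-6, of the TGF-beta pathway that sets body size, stood at 0.79, 1.46 and 2.14 in the 3 mutants in the authors' deposited table (adjusted p = 7.67e-03, 5.43e-07 and 7.13e-15). The p38 kinase gene pmk-2 was at 0.63, 1.2 and 2.26 in the authors' deposited table, and rose in the double (adjusted p = 7.34e-04) and quadruple mutant (adjusted p = 2.14e-14). For daf-4, the type II TGF-beta receptor gene, the authors' deposited table gives 0.40, 0.47 and 0.73, with a call in the quadruple mutant alone (adjusted p = 0.0207). The values of daf-1 were 0.32, 0.44 and 0.51 in the authors' deposited table, without a call. The remaining members, cbp-1 and dbl-1, stood at 0.21 and 0.11 in the quadruple mutant in the authors' deposited table, also without a call. Among 19 TGF-beta signalling genes, 6 rose and 1 fell in the quadruple mutant (Fisher's exact test for higher calls, adjusted p = 0.144). Besides sma-6 and daf-4 they included the Smad genes sma-4 and daf-14, at 0.81 and 0.78 in the authors' deposited table. Of 12 genes of the p38 innate immunity pathway, 3 rose in the double and 1 in the quadruple mutant, and neither excess passed (adjusted p = 0.354 and 1 by Fisher's exact test).

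Loss of mir-58 alone was set against wild type at the same collection time. Of 1214 genes called, 945 (77.8%) were lower and 269 higher. By list median, sperm, adult cuticle and yolk genes were lowest. Of 147 cuticle collagens, 80 fell and 1 rose, with a median log2 fold change of -0.86 (93 fell adjusted over the list alone; Fisher's exact test, adjusted p = 4.04e-58). In the authors' deposited table col-63 was at -6.18, col-175 at -5.38, col-112 at -4.21 and col-38 at -3.96. The adult cuticle and hypodermis list had 11 of 15 genes lower and none higher, at a median of -2.41 (14 adjusted over the list alone; adjusted p = 4.63e-10 by Fisher's exact test). Among its members were col-120 at -4.86 and col-181 at -3.67 in the authors' deposited table. Of 37 sperm genes, 24 fell and none rose (28 adjusted over the list alone), with a median of -3.15 and adjusted p = 7.24e-20 by Fisher's exact test. The sperm phosphatase gene gsp-3 was at -3.63 and ssp-16 at -3.92 in the authors' deposited table. Major sperm protein (msp) genes are near-identical copies, so their values are uncertain. Without them, 13 of 21 sperm genes fell (Fisher's exact test, adjusted p = 2.02e-11).

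Of 5 yolk protein genes 4 fell in mir-58, with a median of -2.17 (Fisher's exact test, adjusted p = 4.12e-04). The yolk genes vit-2 and vit-6 stood at -2.17 and -2.26 in the authors' deposited table. Of 33 oogenesis and eggshell genes, 13 fell and 1 rose (23 fell adjusted over the list alone; Fisher's exact test, adjusted p = 2e-07), and 7 fell at a threshold of 0.01. The members with the smallest p-values, C44B12.5 and C44B12.1, were at -4.20 and -3.79 in the authors' deposited table. The eggshell genes cpg-1 and cpg-2, which the rule picked in the multiple mutants, were at -0.86 and -0.70 in the authors' deposited table. The member that rose, lin-41, also stands on the heterochronic list, of which 3 of 18 genes rose and 2 fell (adjusted p = 0.0163 for higher calls by Fisher's exact test). These were lin-41 at 0.97, hbl-1 at 0.72 and daf-12 at 0.58 in the authors' deposited table, all regulators of the timing of larval development. Germline proliferation and meiosis genes fell in 11 of 38 cases (15 adjusted over the list alone; adjusted p = 5.94e-05 by Fisher's exact test) and in 3 at a threshold of 0.01, among them pgl-3, a P granule component, at -0.97 in the authors' deposited table. Markers of the vulva at L4 gave 1 call in 19 genes, him-4 at 0.66 in the authors' deposited table.

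Of 76 ribosomal protein genes, 19 fell and 6 rose in mir-58, and both excesses passed Fisher's exact test (adjusted p = 4.66e-07 for lower and 9.51e-03 for higher calls). In the authors' deposited table rps-30 was at 3.49 and rpl-19 at 2.93, against -2.26 for rps-9 and -1.83 for rpl-14. Immune effector genes rose in 5 of 35 cases and fell in 5 (adjusted p = 1.72e-03 and 0.157 by Fisher's exact test), with the thaumatin-like gene thn-2 at 1.52 and T24B8.5 at -2.39 in the authors' deposited table. Neuronal genes had a median of 0.33, above the medians of all random lists drawn, yet 3 of 53 were called. These were unc-104, unc-13 and unc-31, genes of axonal transport and secretion, at 1.02, 0.89 and 0.79 in the authors' deposited table. A median of this size was not particular to neurons. The egg laying circuit and uterus list stood at 0.34, the p38 pathway at 0.325 and TGF-beta signalling at 0.3, while intestinal genes stood at -0.1. The insulin and DAF-16 list had 3 of 24 genes higher and 2 lower (Fisher's exact test, adjusted p = 0.0341 for higher calls). Of 37 muscle genes 6 fell and 2 rose, at a median of -0.14, and the excess of lower calls did not pass (adjusted p = 0.0715 by Fisher's exact test). The lowest values among called genes in the authors' deposited table were those of ttr-14 (-6.51), col-63, col-175, ZK1053.6 (-5.28), col-60 (-5.27), F25H5.8 (-5.26), F07D3.3 (-5.24) and dao-4 (-5.15). The highest in the authors' deposited table were chil-28 (5.26), B0507.6 (4.35), H31B20.1 (4.33), fbxa-12 (4.24), ins-16 (4.15), fbxa-136 (3.96), sri-70 (3.88) and rps-30.

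**Figure D1:**
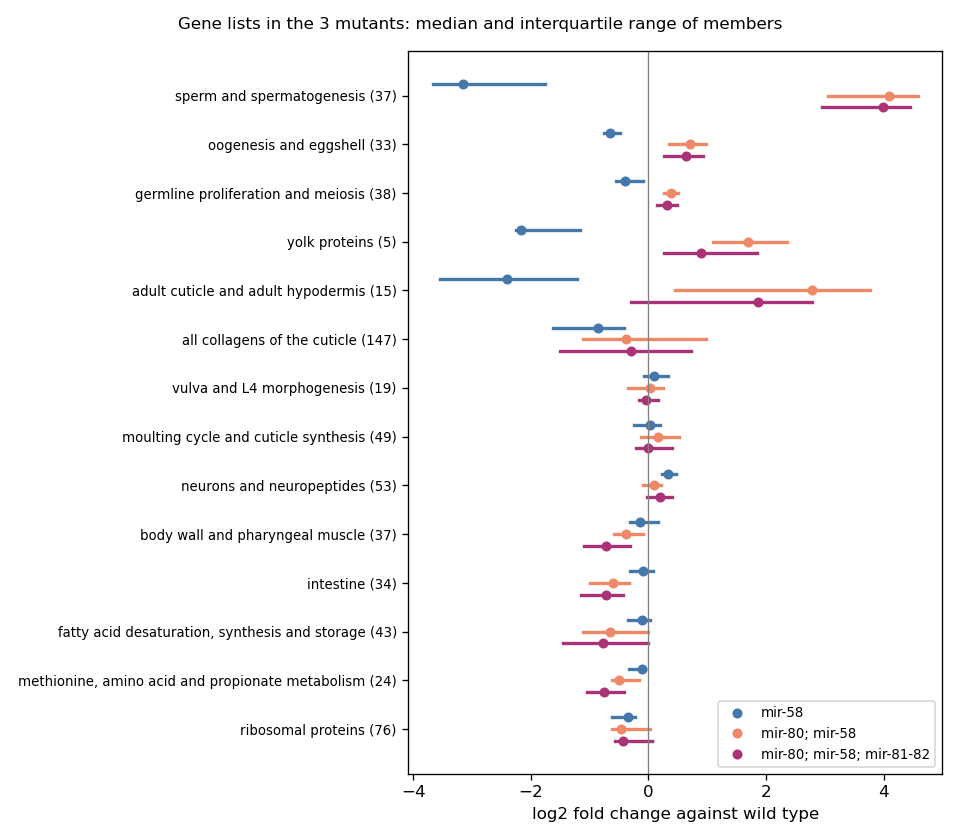
Median (points) and interquartile range (lines) of the log2 fold change against wild type over the members of 14 gene lists, with the number of listed members in brackets, for each of the 3 mutants. The sperm list lies at -3.15 in mir-58 and at 4.09 and 3.99 in the multiple mutants, while the vulva list lies near 0 in all 3.

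In the double mutant 2670 genes were called, 1715 higher (64.2%) and 955 lower. Sperm, oocyte, yolk and adult cuticle genes, lower in mir-58, were higher here. Of 37 sperm genes 33 rose and none fell, with a median of 4.09 (33 adjusted over the list alone, where 1 also fell; adjusted p = 9.31e-27 by Fisher's exact test). Without msp genes 17 of 21 rose. In the authors' deposited table ssq-1 was at 4.50, msp-81 at 4.60 and ssq-2 at 4.09. The adult cuticle list had 10 of 15 genes higher and 3 lower at a median of 2.78 (adjusted p = 3.18e-06 for higher calls by Fisher's exact test), and the members with the smallest p-values were col-129 at 3.96 and col-139 at 3.93 in the authors' deposited table. Of 33 oogenesis and eggshell genes 13 rose and none fell (15 adjusted over the list alone; Fisher's exact test, adjusted p = 1.25e-04). Among 5 yolk genes 3 rose (adjusted p = 0.0444 by Fisher's exact test), with vit-6 at 2.35 and vit-2 at 1.70 in the authors' deposited table. Germline proliferation genes rose in 3 of 38 cases, which did not pass (adjusted p = 1 by Fisher's exact test). The translational repressor gene gld-1 was the strongest of them by p, at 0.97 in the authors' deposited table.

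Collagens as a whole went both ways in the double mutant, with 43 of 147 lower and 31 higher (Fisher's exact test, adjusted p = 8.69e-18 and 7.94e-04). Without genes of the adult cuticle and moulting lists, an alternative chosen after seeing the data, 41 of 134 were lower and 21 higher, and the excess of higher calls no longer passed (Fisher's exact test, adjusted p = 1.40e-18 and 0.0540). The lower ones included col-156 at -2.32 in the authors' deposited table, and the higher ones col-81 at 4.17 and col-88 at 3.52. Intestinal genes fell in 15 of 34 cases and rose in 2, at a median of -0.60 (19 lower adjusted over the list alone; adjusted p = 2.57e-09 by Fisher's exact test). In the authors' deposited table the acid phosphatase gene pho-1 was at -1.39 and lys-5 at -5.56, while the ferritin gene ftn-1 rose to 3.30. Genes of fatty acid synthesis and storage fell in 19 of 43 cases and rose in 2 (22 fell adjusted over the list alone; Fisher's exact test, adjusted p = 1.21e-11). Among them the authors' deposited table gives acs-2, an acyl-CoA synthetase gene, at -2.15, the elongase genes elo-5 and elo-6 at -1.93 and -1.77, and the desaturase gene fat-7 at -1.68. Of 24 methionine, amino acid and propionate genes 6 fell and 1 rose (adjusted p = 0.0105 by Fisher's exact test). Muscle genes fell in 6 of 37 cases and none rose, at a median of -0.38, which did not pass (adjusted p = 0.0750 by Fisher's exact test). Ribosomal protein genes fell in 14 of 76 cases and rose in 5 (adjusted p = 7.94e-04 for lower calls by Fisher's exact test). Immune effectors gave 6 higher and 8 lower calls in 35 genes (adjusted p = 0.422 and 4.14e-03 by Fisher's exact test), and the starvation and dauer list had 7 of 27 genes lower (Fisher's exact test, adjusted p = 4.14e-03). The insulin and DAF-16 list had 5 of 24 genes lower and 2 higher (adjusted p = 0.0474 for lower calls by Fisher's exact test).

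The lowest called genes of the double mutant in the authors' deposited table were K06H6.1 (-6.71), K06H6.2 (-5.79), F15E11.15 (-5.70), lys-5, clec-47 (-5.12), C14C6.8 (-4.32), T02B5.1 (-4.19) and C14C6.7 (-4.10). The highest in the authors' deposited table were F37E3.3 (6.25), B0507.6 (6.11), Y53C10A.10 (6.03), F49C12.2 (5.90), B0524.2 (5.88), C33H5.1 (5.80), F47B3.2 (5.76) and R08A2.3 (5.76).

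The quadruple mutant had the most calls, 3920 genes, with 2318 higher (59.1%) and 1602 lower. The median of all listed genes was 0.11 here, against -0.06 in mir-58 and 0.08 in the double mutant. Sperm genes again rose in 33 of 37 cases at a median of 3.99 (adjusted p = 1.78e-22 by Fisher's exact test, and 17 of 21 without msp genes). Oogenesis and eggshell genes rose in 11 of 33 cases (15 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0199) and in 7 at a threshold of 0.01. The adult cuticle list had 8 of 15 genes higher and 4 lower (adjusted p = 2.24e-03 for higher calls by Fisher's exact test), and 2 of 5 yolk genes rose, which did not pass (adjusted p = 0.428 by Fisher's exact test). Collagens fell in 48 of 147 cases and rose in 25 (Fisher's exact test, adjusted p = 5.31e-13 for lower calls).

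Metabolic, intestinal and muscle genes were lower in the quadruple mutant. Fatty acid genes fell in 24 of 43 cases and rose in 4, at a median of -0.77 (25 lower adjusted over the list alone; adjusted p = 1.26e-12 by Fisher's exact test). In the authors' deposited table acs-2 was at -3.77, fat-7 at -2.77, elo-5 at -2.30 and F08A8.2 at -3.25. The lipase genes lipl-1 and lipl-2 went the other way, at 1.98 and 2.34 in the authors' deposited table. Intestinal genes fell in 18 of 34 cases (21 adjusted over the list alone; Fisher's exact test, adjusted p = 3.38e-09), with pho-1 at -2.14 and the sodium-proton exchanger gene nhx-2 at -1.16 in the authors' deposited table. Muscle genes fell in 19 of 37 cases and rose in 2, at a median of -0.73 (20 lower adjusted over the list alone; adjusted p = 2.71e-09 by Fisher's exact test). The troponin genes tnt-2 and tni-1 were at -1.77 and -1.31, and the actin gene act-3 at -1.10, in the authors' deposited table. Of 24 methionine, amino acid and propionate genes 14 fell and 1 rose (16 lower adjusted over the list alone; Fisher's exact test, adjusted p = 5.04e-08). They included sams-1, an S-adenosylmethionine synthetase gene, at -1.54 and pccb-1, of propionyl-CoA carboxylase, at -1.27 in the authors' deposited table. Smaller excesses of lower calls were found for starvation and dauer genes (11 of 27; adjusted p = 1.80e-04), oxidative and xenobiotic genes (11 of 34; adjusted p = 1.81e-03) and heat shock and unfolded protein genes (6 of 18; adjusted p = 0.0243), each by Fisher's exact test. The starvation and dauer list shares members with the fatty acid list, among them acs-2 and fat-7, so its excess in either multiple mutant is not a separate finding.

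Immune effectors of the quadruple mutant moved in both directions, 12 of 35 higher and 11 lower (adjusted p = 0.0113 and 2.14e-03 by Fisher's exact test). The lysozyme gene lys-10 was at 6.39, thn-1 at 4.87, thn-2 at 4.28 and lys-7 at 2.42 in the authors' deposited table. Ribosomal protein genes gave 14 lower and 9 higher calls (adjusted p = 0.0585 for lower calls by Fisher's exact test), with rps-16 at -4.54 and rpl-14 at -4.15 against rpl-19 at 3.56 in the authors' deposited table. Calls without an excess in this mutant by Fisher's exact test were found for neurons (4 higher and 1 lower of 53), hypodermis and seam (3 higher of 18), moulting (8 higher and 4 lower of 49), the microRNA pathway (3 higher and 2 lower of 30), the egg laying circuit and uterus (2 higher of 19), insulin and DAF-16 genes (4 higher and 5 lower of 24) and the heterochronic pathway (1 higher and 1 lower of 18). The vulva and the early embryo lists gave none in 19 and 9 genes. The lowest called genes in the authors' deposited table were dyf-13 (-8.35), a gene of the cilium, clec-47 (-6.99), F15E11.15 (-6.90), K06H6.1 (-6.61), F15E11.12 (-5.03), ugt-63 (-5.03), lys-5 (-4.96) and cut-1 (-4.87). The highest in the authors' deposited table were B0563.9 (7.28), T26H5.10 (7.28), C02E7.10 (7.09), B0507.6 (6.90), W08A12.4 (6.58), Y53C10A.10 (6.40), lys-10 and F07E5.9 (6.23).

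Successive genotypes were compared by the difference of their fold changes, which has no test. From mir-58 to the double mutant the median difference was 7.57 over sperm genes, 5.57 over the adult cuticle list, 3.87 over yolk genes and 1.35 over oogenesis genes, against 0.04 over all listed genes. From the double to the quadruple mutant it was -0.10, -0.56, -0.04 and -0.08 for the same lists, against 0.00 over all genes. Muscle genes differed by -0.34 in that step, and methionine, amino acid and propionate genes by -0.29. Reported targets differed by 0.13 and 0.24 in the 2 steps. Among the 2318 genes higher in the quadruple mutant, 207 stepped up by at least 0.5 at each added deletion from a value above 0 in mir-58, and 108 of the 1602 lower genes stepped down in the same way. Of these, 124 and 86 were also called in the double mutant. The steps have no test, no number expected by chance was computed, and these genes were chosen after the data were seen. They included ilys-2, a lysozyme gene, at 1.26, 5.01 and 5.80 and clec-47 at -1.52, -5.12 and -6.99 in the authors' deposited table.

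**Figure D2:**
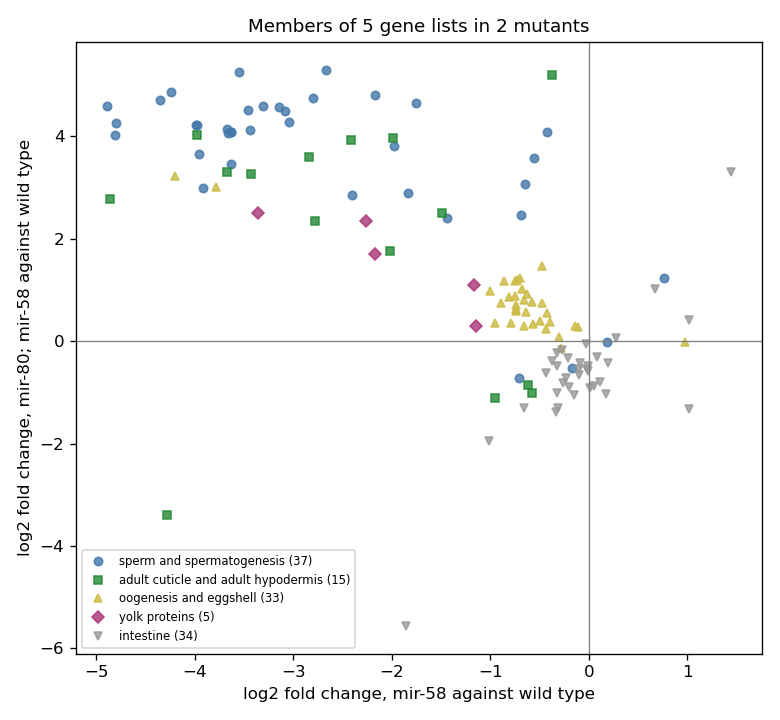
Log2 fold change against wild type in mir-58 (horizontal axis) and in the double mutant (vertical axis) for each member of 5 gene lists, as given in the authors' deposited table. Sperm genes, such as gsp-3 at -3.63 and 3.46, lie mostly at the upper left, and intestinal genes lie mostly below 0 on the vertical axis.

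Calls of the double and quadruple mutants overlapped in 1595 higher and 893 lower genes, and none went opposite ways. Independent lists would share 244 and 93.8, and unchanged groups compared with the same wild type shared 699 and 350 on average in simulations. The mir-58 and double mutant calls shared 131 higher and 218 lower genes, against 28.3 and 55.3 for independent lists and 134 and 245 in the simulations. Opposite calls were as many as 443 genes lower in mir-58 and higher in the double mutant, against 99.4 for independent lists and 4.88 in the simulations. With the quadruple mutant mir-58 shared 165 higher and 249 lower genes, against 38.2 and 92.8 for independent lists and 155 and 350 in the simulations. In opposite directions 440 genes were lower in mir-58 and higher in the quadruple mutant, against 134.3 for independent lists and 9.09 in the simulations. The overlaps of mir-58 with the other mutants in the same direction were thus close to or below the simulated ones. The simulations treat every call as noise, in numbers that unchanged groups would not give, so their overlaps are set high. They also gave 4.88 and 9.09 opposite calls where 443 and 440 were seen, so they do not describe these data. How much of these overlaps comes from the common wild type cannot be told. The wild-type samples could not be split here, so part of the overlap of the double and quadruple mutants may also come from them. In all 3 mutants 123 genes were higher and 211 lower, against 4.02 and 5.44 for independent lists and 92.0 and 135 in the simulations. Named after their values were seen, sri-70 (3.88, 4.27 and 5.50) and T08E11.1 (2.87, 4.39 and 4.85) were among the former, and asp-12, an aspartyl protease gene (-2.05, -3.08 and -2.72), and rps-9 (-2.26, -2.21 and -2.36) among the latter, in the authors' deposited table.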

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

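The thresholds of adjusted p under 0.01 and of at least 1.5-fold were planned for the counts of genes changed. Their use on the list counts, and all other alternatives, were chosen after seeing the data. Under adjusted p of 0.01 the calls in mir-58 dropped to 753 from 1214, as a stricter threshold must give fewer. The counts of the double and quadruple mutants, 1914 and 2844, stayed within 1.5 times those at 0.05. A change of at least 1.5-fold left 1131 calls in mir-58 and removed none in the other mutants. At adjusted p under 0.1 the counts were 1655, 3223 and 4659. With only names matched to 1 annotated gene they were 1165, 2576 and 3765. Of 24 list counts, 21 stayed within 1.5 times at adjusted p under 0.01. The exceptions were oogenesis genes lower in mir-58 (7 in place of 13), oogenesis genes higher in the quadruple mutant (7 in place of 11) and germline genes lower in mir-58 (3 in place of 11). Leaving out the 162 genes with an adjusted p of 1 in every comparison from the background changed none of the 37 list calls. No paired analysis was possible because the table holds comparisons and no values per replicate. For the same reason other normalisations, tools, filters, leave-one-out fits, other set tests and other splits of the samples were not run. Depth is unknown, so its effect on genes with few reads could not be assessed.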

Other observations

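Gene families sharing a name prefix, tested after the data were seen, gave further groups, some of which share members with the lists (Fisher's exact test, adjusted over 642 tests, of which 33 passed). Histone genes rose in 17 of 32 cases in the quadruple mutant at a median log2 fold change of 1.49 (Fisher's exact adjusted p = 1.46e-05). Their reads may be shared between near-identical copies, which was not tested, as for the msp genes, without which 17 sperm genes rose in the quadruple mutant. F-box A (fbxa) genes rose in 42 of 151 cases (Fisher's exact adjusted p = 3.73e-04), with fbxa-165 at 4.94 and fbxa-162 at 3.77 in the authors' deposited table. Subunits of the vacuolar proton pump (vha) fell in 12 of 18 cases in the quadruple mutant and in 7 in the double mutant (Fisher's exact adjusted p = 5.85e-07 and 1.39e-03). The authors' deposited table gives vha-12 at -1.08 and vha-15 at -0.86 in the quadruple mutant. Translation initiation factor (eif) genes fell in 7 of 11 cases there (Fisher's exact adjusted p = 7.18e-04), glucuronosyltransferase (ugt) genes in 19 of 63 (Fisher's exact adjusted p = 2.45e-04), saposin-like (spp) genes in 9 of 21 (Fisher's exact adjusted p = 2.28e-03) and aspartyl protease (asp) genes in 6 of 10 (Fisher's exact adjusted p = 3.19e-03). Neurotransmitter transporter (snf) genes followed the sperm genes, with 5 of 12 lower in mir-58 (Fisher's exact adjusted p = 7.78e-03) and 8 higher in both the double and the quadruple mutant (Fisher's exact adjusted p = 2.26e-04 and 1.46e-03). In mir-58, unc genes rose in 10 of 91 cases (Fisher's exact adjusted p = 1.34e-04) and C-type lectin (clec) genes in 13 of 163 (Fisher's exact adjusted p = 1.54e-04).

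Of the tests that follow, those of stage, calendar age, paralogs, coordinated change and the X deletion were chosen after the result was seen. The list medians of sperm, oogenesis, yolk and adult cuticle genes lay below 0 in mir-58 and above 0 in both multiple mutants, although the higher calls of yolk genes did not pass in the quadruple mutant. Calendar age cannot account for the lower values in mir-58, which was collected at the same 33 h as wild type. For the higher values of the multiple mutants, the comparison cannot decide on a steady rise with age. The double and quadruple mutants differ in genotype as well as in collection time, so an effect of genotype could hide such a rise. The quadruple mutant, collected later than the double, was not higher: the median difference over the 90 genes was -0.11 (interquartile range -0.24 to -0.02). A rise that ended before the double mutant was collected was not tested, and genes are not independent replicates. The stage of the animals at collection stays open as a candidate explanation. Of 38 germline proliferation and meiosis genes, which are not among the 4 lists, 100% had a higher value in the double mutant than in mir-58. A direct effect of the microRNAs on the germline could give the same, so this separates neither. Such an effect would have to change direction between the 2 strains, where the list medians were -0.395 in mir-58 and 0.375 in the double mutant. The prediction for stage also needed an excess of calls on the moulting list in a mutant, and this part was not met. Of 49 moulting genes, 1 rose and 4 fell in mir-58, 7 and 3 in the double and 8 and 4 in the quadruple mutant. No excess passed Fisher's exact test, which does not exclude a difference of stage. Collagens outside the adult cuticle and moulting lists, not part of the prediction, had 70 of 134 genes lower and 1 higher in mir-58 (Fisher's exact test, adjusted p = 3.44e-50 for lower calls). In the double and quadruple mutants 41 and 46 of them were lower and 21 and 17 higher. The vulva list does not bear on stage, since animals were collected by vulval structure.

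Some ribosomal protein genes changed strongly, and in both directions, within each mutant, while 51, 57 and 53 of the 76 were not called in mir-58, the double and the quadruple mutant. Reads shared between same-numbered paralogs are argued against as the whole cause, since 4 of the 28 genes called with a change of at least 2-fold (14.3%) have such a paralog. Among all 76 genes 8 have one (10.5%), so the share is not below that of the list, and read sharing stays open as a part of the cause. A length-dependent yield is argued against only for the differences among these genes, with a Spearman rho of 0.0367 between exonic length and fold change across 75 genes in the quadruple mutant (permutation p = 0.754, adjusted p = 0.754 over 3 mutants; genes are not independent replicates). Genes outside the list were not compared by length, so a yield effect on short transcripts as a class was not tested. A coordinated lowering of ribosome synthesis stays open for the list as a whole: 63 of the 76 genes (82.9%) lay below 0 in mir-58 and 56 in each multiple mutant, with medians of -0.34, -0.46 and -0.43, all below those of the random lists drawn. It would not by itself raise the genes called higher. Processed pseudogenes, sample-to-sample differences and strain variants were not tested.

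X-linked genes were more often lower in the multiple mutants, 10.6% against 5.21% of autosomal genes in the double (adjusted p = 1.25e-19) and 13.8% against 9.34% in the quadruple mutant (adjusted p = 4.07e-10, both by two-sided Fisher's exact test). The X deletion of the quadruple mutant is argued against as the cause, because the ratio of these shares was already 2.03 in the double mutant, which lacks that deletion. The tissue makeup of the animals may account for the pattern, since X-linked genes are known to be little used in the germline: the median on X minus that on autosomes was -0.19 in both multiple mutants and 0.10 in mir-58, the direction opposite to that of the sperm and germline genes in each. This remains a hypothesis, and an effect of the microRNAs on X-linked genes was not tested.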
